A study of Manihot esculenta with 14 samples.

How the data were processed

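The samples were bulk leaf RNA of cassava (Manihot esculenta), cultivar HuayBong 60. Per the labels' protocols, 500 ng of total RNA per sample went into library preparation by version 1.1 of the Lasy-Seq protocol, a multiplexed RNA-seq method. The leaves were the uppermost on the stem, per the series' design text. The design text gives more than 1 number of nymphs per plant, and the labels do not say which number each library had.

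The authors deposited a table of raw counts per gene and a table of normalised values. The submitters' processing notes name bcl2fastq, Trimmomatic, HISAT2, featureCounts and DESeq2, without versions. The genome build, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The counts are whole numbers, 1 column per library. The second deposited table holds a signal: in all 14 libraries 100.00% of its genes equalled the counts divided by a size factor, within 0.01 of the larger of 1 and the value, and that factor was the median-of-ratios factor of the library. That table was used for this check alone, and every value reported comes from the counts.

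Groups were taken from the sample labels: control (n = 2) and 1, 3, 5 and 10 days after inoculation (n = 4, 2, 3 and 3). Nothing in the labels says that replicates came from separate plants, so the p-values measure the spread between these samples, which can be partly technical. Counts of the 14 pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom between 8.93 and 67.9 over genes with at least 20 counts in the pair, so no library was treated as a copy of another.

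Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Genes were kept with filterByExpr over the 5 groups, which left 17138 of 25887 genes and 99.86% of the counts in the library with the lowest share. Libraries were scaled with TMM factors, which had a mean of 1.09 in the control and 0.874 at day 10. All 14 libraries entered a single edgeR quasi-likelihood fit of 5 groups with a robust estimate of the spread. Its common biological coefficient of variation was 0.271 and its residual degrees of freedom 9. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, each day against the control, day 10 against day 1, and all groups in a joint test. Standard errors are the log2 change divided by the square root of F. CPM values use the TMM-scaled library sizes, and principal components use log2 CPM with a prior count of 2. Correlations with the day were tested with 100000 resamples in two-sided permutation tests. Falls at day 10 were also tested against a nonzero shift with edgeR's glmTreat and its worst-case null, a test chosen after seeing the data. Intervals from counts cover counting error only.

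Depth ranged from 3137131 to 12477047 counts per library. On simulated counts with 200 changed genes, the day 10 comparison with the control recovered 17 of 100 genes changed 2-fold and 66 of 100 changed 4-fold among 16747 genes, with 3 false among 86 calls. DESeq2 on the same counts recovered 32 and 75, with 26 false among 133 calls. By edgeR, the day 1 comparison recovered 23 and 69 among 16763 genes, day 3 recovered 11 and 61 among 16800, day 5 recovered 13 and 64 among 16771, and day 10 against day 1 recovered 37 and 74 among 16747. In the data 26.3% of the genes tested were called at day 10, a far larger share than the 200 simulated. The adjusted p depends on that share, so these rates do not give the recovery in the real day 10 comparison.

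The IDs are given as in the count table. A table of RefSeq gene names for the assembly M.esculenta_v8 matched 0 of the 25887 IDs, so the files used here do not pair the IDs with names. No gene is described by function, and 30 gene lists planned from product names were not tested. For each comparison 2 IDs that rose and 2 that fell are printed: those with the largest log2 change among called genes with a mean of at least 10 CPM over the libraries compared and no overlap between the libraries of the 2 groups. Of 16558 genes with at least 100 counts, 2 pairs had counts within 2% of each other, or within 1 count, in every library.

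The tests, the rule for printed IDs and the main alternatives were fixed before the data were examined. The alternatives were DESeq2's size factors in edgeR, no filter on low counts, DESeq2, limma-voom, a non-robust estimate of the spread, the replicate number as a block, only the libraries compared, and each library left out. Scaling to the total count, thinning to the smallest library, removal of the 100 most abundant genes, removal of the day 3 libraries, the comparisons of day 5 with day 1 and day 10 with day 5, all alternatives for the genes shared by day 5 and day 10, and limma-voom and the fit of only the libraries compared for the named genes were chosen after seeing the data.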

Results

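Leaf RNA of the cassava cultivar HuayBong 60 was counted per gene in 14 libraries, from plants without the cassava mealybug and from plants carrying it. The mealybug, Phenacoccus manihoti, feeds on sap, and leaf curling on infested plants is the subject of the study. The libraries fell into 5 groups: control leaves (n = 2) and leaves collected at 1 day (n = 4), 3 days (n = 2), 5 days (n = 3) and 10 days (n = 3) after inoculation. Total counts per library were 6874728 and 12477047 in the controls, and 5279424, 11654930, 5937217 and 5258290 at day 1. They were 3137131 and 8084041 at day 3, 6747409, 8510608 and 6501032 at day 5, and 10202986, 5532689 and 5743958 at day 10. Of 25887 genes in the table, 3542 had 0 counts in all libraries and 17138 were tested. The labels do not give the day on which the control leaves were taken, so leaf age and inoculation are not separated in any comparison with the control. Uninoculated leaves are not labelled for any of the 4 days, so leaf age and time since inoculation are not separated between the days either. Nor do the labels give the number of nymphs for each library, so differences between libraries or days may include that number.

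Which genes changed over the time course was the first question. In a single test over the 5 groups, 3158 of 17138 genes (18.4%) differed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of these, 1412 (44.7%) lay above the control at all 4 days, 998 (31.6%) lay below it at all 4 days, and 748 (23.7%) had mixed signs. Among all tested genes 58.4% lay on one side of the control at all 4 days, beside 44.7% in simulated unchanged groups that shared the same controls. The simulation gave a gene the same spread in every group, the control included. The count over the 5 groups was 4840 with DESeq2, and without control replicate 1, control replicate 2 or day 10 replicate 2 it was 1331, 1842 and 2054.

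The first principal component held 32.1% of the variance and placed the libraries in the order of the sampling days by group mean. Its mean was -69.6 ± 13.1 in the control (SD, n = 2), -25.8 ± 21.6 at day 1 (SD, n = 4), 5.35 ± 1.77 at day 3 (SD, n = 2), 15.2 ± 20.2 at day 5 (SD, n = 3) and 62.0 ± 24.8 at day 10 (SD, n = 3). Over the 12 libraries of inoculated plants the component correlated with the day (Pearson r = 0.885, permutation p = 5e-05, adjusted p = 1e-04; Spearman rho = 0.890, permutation p = 0.00023, adjusted p = 0.00046). Leaving out 2 of the 3 day 10 libraries, in each choice of 2, gave r between 0.805 and 0.902. The second component held 16.7% of the variance and set the day 3 libraries apart, at -51.2 for replicate 1 and 49.1 for replicate 2. The day 1 libraries lay on the side of day 3 replicate 1, with a mean of -32.75 and a range from -62.8 to -2.8. The means of the control, day 5 and day 10 were 28.95, 17.8 and 7.23.

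**Figure D1:**
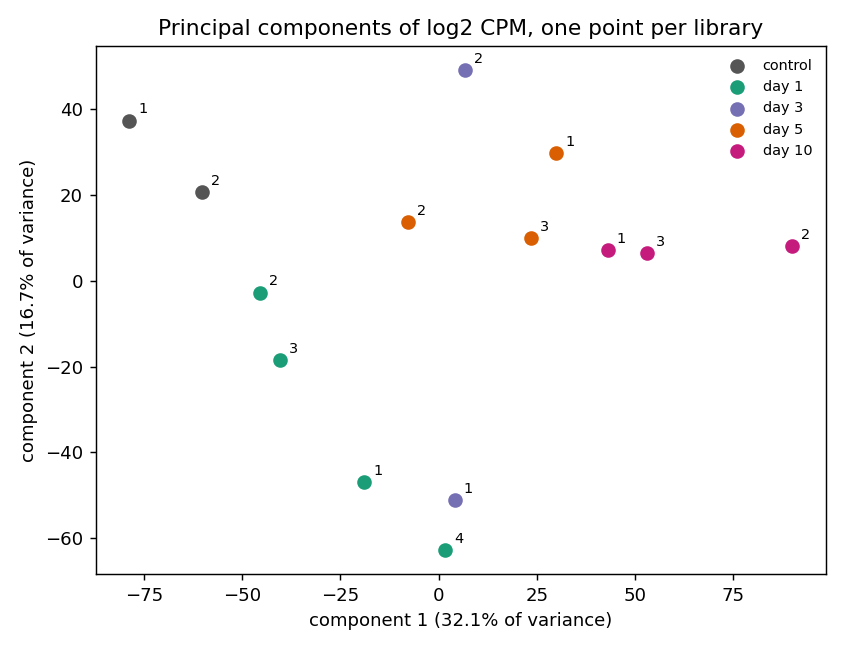
Each point is a library, placed by its first (horizontal, 32.1% of variance) and second (vertical, 16.7% of variance) principal component of log2 CPM (counts scaled to library size); colours mark the groups and digits the replicate numbers. The day 3 libraries lie at -51.2 and 49.1 on the second component, and the day 1 libraries between -62.8 and -2.8.

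The share of the counts in the genes most abundant over all libraries was highest at day 10. The 100 most abundant genes, ranked by their mean share over all libraries, held 18.5% ± 0.932 of the counts in the control (SD, n = 2), 24% ± 3.69 at day 1 (SD, n = 4), 21.8% ± 3.81 at day 3 (SD, n = 2), 24.6% ± 1.61 at day 5 (SD, n = 3) and 31.3% ± 0.629 at day 10 (SD, n = 3). Of these genes 34 rose and 2 fell at day 5, and 52 rose and 16 fell at day 10, with a median log2 change of 1.26 at day 10. Day 1 replicate 4, at 29.5%, lay near the day 10 libraries. None was called at day 1 or day 3 with edgeR (0 of 100 each), where 57 and 38 had an unadjusted p under 0.05, and DESeq2 called 48 at day 1 and 2 at day 3. The share correlated with the day over the 12 libraries of inoculated plants (r = 0.739, permutation p = 0.00736; rho = 0.702, permutation p = 0.0141; the adjusted values over the 2 relations computed were the same). Without 2 of the 3 day 10 libraries r was 0.520 to 0.568. Only 2 of the 14 libraries in the ranking are controls, which favours genes abundant in inoculated leaves. Part of the gap from the control, and of the rises among these genes, can come from that choice. The share of each group's own most abundant genes was not computed.

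**Figure D2:**
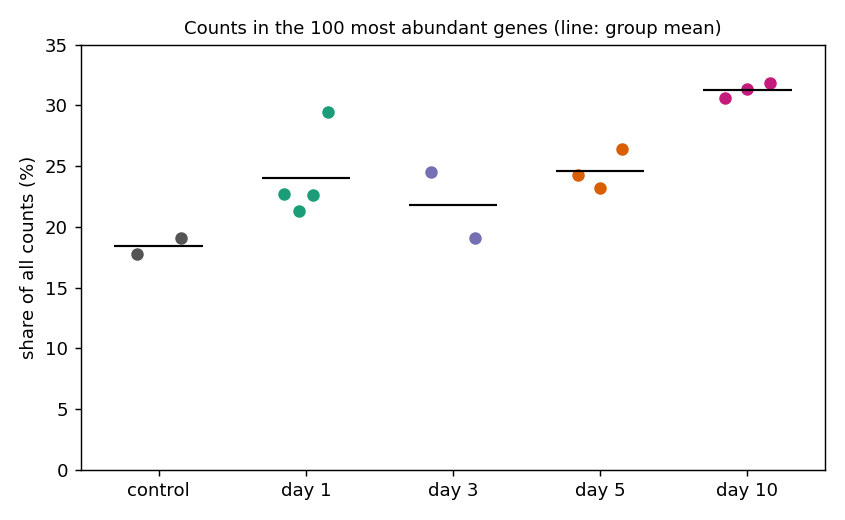
Points are libraries and lines are group means. The vertical axis is the percentage of all counts in the 100 genes with the highest mean share over all libraries. The day 10 libraries lie between 30.6% and 31.8%, above the control libraries at 17.8% and 19.1%.

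At 1 day 11 of 17138 genes rose and 8 fell, and all 19 changed at least 2-fold, with a median log2 change of 1.71 for the rises and -1.82 for the falls. Manes.04G013900 went from 12.5 ± 5.08 CPM in the control (SD, n = 2) to 54.2 ± 14.9 CPM (SD, n = 4), and Manes.02G115400 from 19.7 ± 2.47 to 69.0 ± 17.1 CPM. Manes.15G054200 went from 25.9 ± 0.187 to 4.74 ± 2.37 CPM and Manes.02G037500 from 27.5 ± 5.68 to 4.34 ± 2.35 CPM. The 11 rises include 2 genes with near-identical counts in every library, so the reads of that pair of IDs cannot be assigned with certainty to separate genes.

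In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment the log2 changes at day 1 were 2.10 (SE 0.30, adjusted p = 0.0116), 1.80 (SE 0.24, adjusted p = 0.00922), -2.41 (SE 0.40, adjusted p = 0.0343) and -2.65 (SE 0.37, adjusted p = 0.00922) in that order. At an unadjusted p under 0.05 there were 3301 genes. The number called was 1032 with DESeq2 (828 rose and 204 fell), 105 after thinning (86 and 19), 121 with limma-voom (62 and 59), 478 without the day 3 libraries (371 and 107), 238 from the libraries of both groups alone, and 7, 568, 5 and 8 without day 1 replicates 1 to 4. Without control replicate 1 or 2 it was 0 (1082 and 2383 genes at an unadjusted p under 0.05), which ended all 4 named calls. Manes.15G054200 also lost its call without day 1 replicate 1 (adjusted p = 0.130) or replicate 3 (adjusted p = 0.0630), in a range of up to 0.630 over its alternatives.

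At 3 days rises outnumbered falls, 81 to 22. Of the rises 36 were at least 4-fold, against 4 of the falls, and the median log2 change was 1.80 for the rises and -1.72 for the falls. Manes.02G050400 went from 2.94 ± 1.39 CPM in the control (SD, n = 2) to 26.7 ± 14.4 CPM (SD, n = 2) and was at 25.5 ± 8.77 CPM at day 5 and 37.3 ± 6.70 CPM at day 10 (SD, n = 3 each). Manes.10G021200 went from 0.442 ± 0.441 to 22.2 ± 16.3 CPM, with day 3 libraries at 10.7 and 33.8 CPM. It was at 2.17 ± 1.33 CPM at day 5, where edgeR did not call it (adjusted p = 0.261). At day 10 it was at 9.96 ± 9.49 CPM, with libraries between 2.82 and 20.7 CPM, and was called (log2 change 4.25, edgeR adjusted p = 0.00834). Manes.02G175000 went from 23.9 ± 0.374 to 5.37 ± 0.603 CPM and Manes.14G114400 from 20.7 ± 3.85 to 3.47 ± 1.13 CPM.

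The log2 changes of the rises were 3.16 (SE 0.44, adjusted p = 0.0165) and 5.47 (SE 1.06, adjusted p = 0.0469), and of the falls -2.17 (SE 0.36, adjusted p = 0.0194) and -2.65 (SE 0.56, adjusted p = 0.0484), all from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 3446 genes. With all libraries thinned to the smallest depth 92 genes were called, of which only 49 were among the 103 with the same direction. The 103 calls became 956 with DESeq2, 0 from the libraries of both groups alone (3044 at an unadjusted p under 0.05), 0 without control replicate 1 (1691), 2 without control replicate 2 and 361 without day 3 replicate 1. The calls of all 4 named genes ended from the libraries of both groups alone and without either control library, those of Manes.10G021200, Manes.02G175000 and Manes.14G114400 also without day 3 replicate 2, and that of Manes.14G114400 without day 3 replicate 1. With limma-voom the calls of Manes.10G021200 (adjusted p = 0.0912) and Manes.14G114400 (adjusted p = 0.0578) ended, and that of Manes.14G114400 also after thinning (adjusted p = 0.0681), in ranges of up to 0.494 and 0.465 over their alternatives.

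At 5 days 708 genes rose and 383 fell (6.37% of the genes tested). At least 2-fold changes made up 507 of the rises and 279 of the falls, and the median log2 change was 1.26 and -1.28. Manes.09G117300 went from 0.401 ± 0.354 CPM in the control (SD, n = 2) to 21.3 ± 3.65 CPM (SD, n = 3), through 4.09 ± 1.48 CPM at day 1 (SD, n = 4) and 7.75 ± 4.48 CPM at day 3 (SD, n = 2). Manes.12G055201 went from 4.37 ± 0.645 to 105.0 ± 79.9 CPM, with day 5 libraries between 22.5 and 182 CPM. Manes.11G028100 went from 107 ± 60.9 to 6.69 ± 4.49 CPM. Its mean was 13 ± 2.23 CPM at day 1, where edgeR did not call it (adjusted p = 0.0651). Manes.15G129300 went from 28.7 ± 9.31 to 2.58 ± 1.19 CPM.

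In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 change of Manes.09G117300 was 5.87 (SE 0.61, adjusted p = 0.000537) and that of Manes.12G055201 4.57 (SE 0.90, adjusted p = 0.0219), while Manes.11G028100 had -4.0 (SE 0.69, adjusted p = 0.0133) and Manes.15G129300 -3.45 (SE 0.86, adjusted p = 0.0381). The count of 1091 was 1938 with DESeq2, scaling to the total count gave 554 rises and 556 falls, and there were 1950 from the libraries of both groups alone, 5 and 153 without control replicates 1 and 2, and 227 and 396 without day 5 replicates 1 and 3. Without control replicate 1 the calls of Manes.12G055201, Manes.11G028100 and Manes.15G129300 ended, without control replicate 2 those of Manes.12G055201 and Manes.15G129300, and that of Manes.15G129300 also ended without any one of the day 5 libraries. The call of Manes.12G055201 also ended from the libraries of both groups alone (adjusted p = 0.119), and that of Manes.15G129300 without a filter on low counts (adjusted p = 0.0615) and after thinning (adjusted p = 0.0508), in ranges of up to 0.318 and 0.335 over their alternatives.

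By 10 days 2375 genes had risen and 2132 had fallen, 26.3% of the genes tested. Changes of at least 4-fold made up 629 of the rises and 437 of the falls. The genes that rose held 19.1% of the counts in the control and 48.7% at day 10, and the genes that fell 23.0% and 7.75%. Manes.10G144300 went from 15.0 ± 5.49 CPM in the control (SD, n = 2) to 852 ± 287 CPM (SD, n = 3), with 25.5 ± 5.95 CPM at day 1 (SD, n = 4) and 298 ± 177 CPM at day 5 (SD, n = 3). Manes.09G117300 reached 38.2 ± 12.7 CPM, while Manes.07G014300 went from 79.9 ± 36.7 to 6.82 ± 2.40 CPM and Manes.03G019900 from 26.3 ± 7.98 to 1.81 ± 1.09 CPM.

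**Figure D3:**
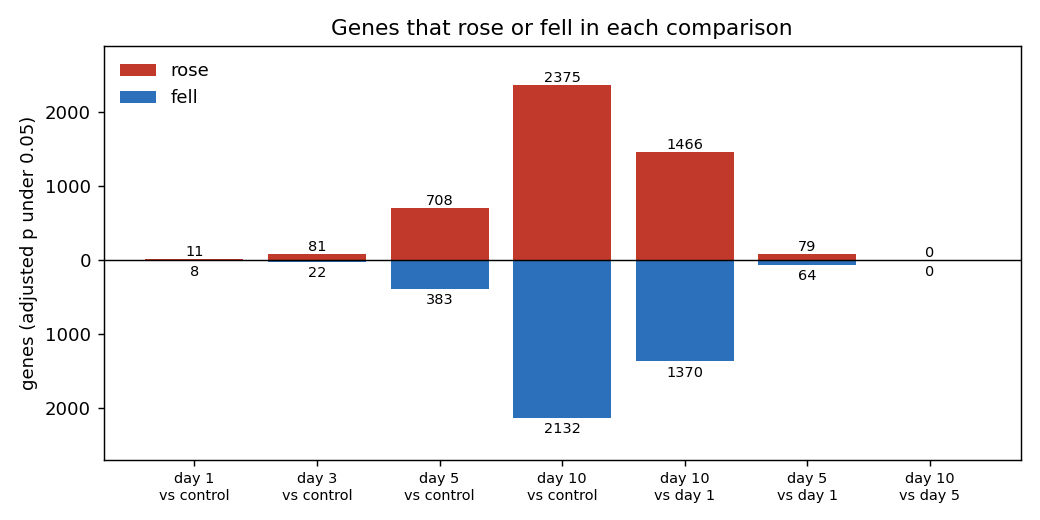
Bars show the number of genes that rose (above the line) or fell (below the line) in each comparison, with an adjusted p under 0.05. The number against the control went from 19 at day 1 to 4507 at day 10. At an unadjusted p under 0.05 in the same edgeR test, not drawn here, the numbers were 3301 and 6577.

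When the tested genes were ranked by mean level over all libraries and divided into 5 equal parts, 238 of 3428 genes rose and 136 fell at day 10 in the lowest part, and 816 of 3428 rose and 553 fell in the highest. A rise at day 10 lifts a gene's own mean, and calls come more easily at high counts, so these numbers do not show that abundant genes rose more often. The log2 change was 6.71 for Manes.09G117300 (SE 0.62, adjusted p = 4.34e-05), 5.82 for Manes.10G144300 (SE 0.81, adjusted p = 0.000693), -3.52 for Manes.07G014300 (SE 0.66, adjusted p = 0.00307) and -3.82 for Manes.03G019900 (SE 0.47, adjusted p = 0.000127) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These 4 genes passed the threshold in all 16 other settings tried. With scaling to the total count, which moved the median log2 change of all genes from -0.02 to -0.34, 1623 genes rose and 4198 fell. DESeq2 called 5025 genes at day 10, beside 1032, 956 and 1938 at days 1, 3 and 5. By edgeR 3301, 3446, 3867 and 6577 genes had an unadjusted p under 0.05 at days 1, 3, 5 and 10. The number of calls therefore grew more steeply than the number of genes at that looser threshold. Without control replicate 1 there were 1548 calls, all 1548 among the 4507, and without control replicate 2 there were 2529.

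**Figure D4:**
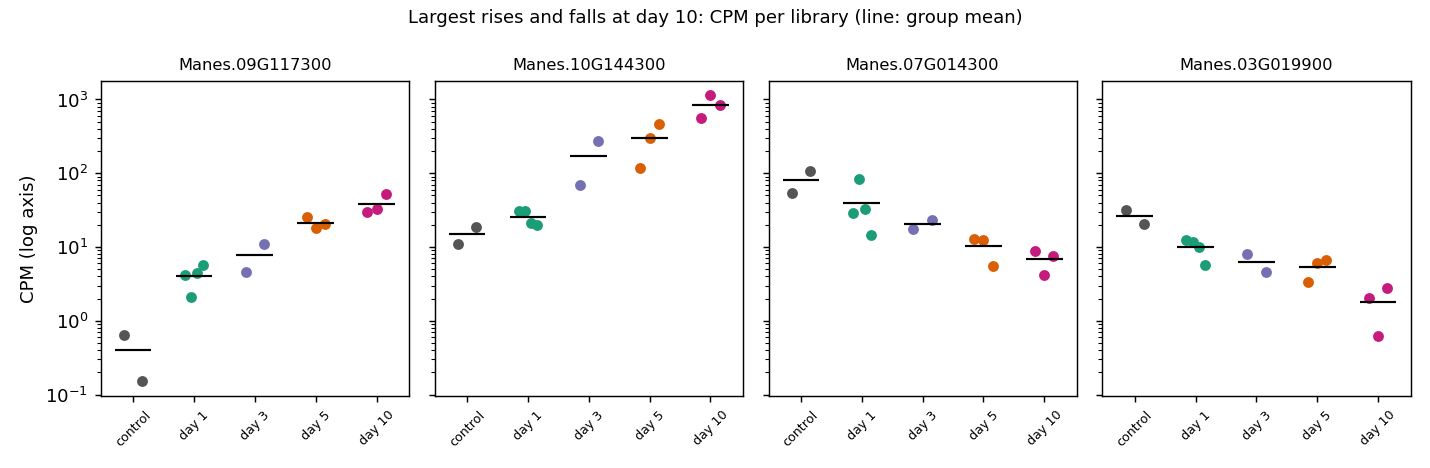
Each panel is a gene named for day 10; points are libraries, lines are group means and the vertical axis is CPM on a log scale. Manes.10G144300 has a mean of 15.0 CPM in the control and 852 CPM at day 10, and Manes.03G019900 26.3 and 1.81 CPM.

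Among the 2375 rises 94.4% lay above the control at day 1, 94.3% at day 3 and 99.5% at day 5, and their median log2 change was 0.64, 0.72, 0.89 and 1.42 at days 1, 3, 5 and 10. The median of the 2132 falls was -0.46, -0.64, -0.72 and -1.20. The genes were chosen by their change at day 10 against the same control libraries, which raises these shares and medians at the earlier days. In 20 simulations of unchanged groups, as many genes ranked first by p for a rise at day 10 lay above the control in 89.5%, 83.2% and 87.6% of cases at days 1, 3 and 5. The simulations gave a gene the same spread in every group. In the data the median SD of log2 CPM over genes was 0.169 in the control and 0.292 to 0.329 in the other groups. Simulated shares and correlations may therefore not match those of unchanged groups with these controls. The falls lay below the control in 92.6%, 95.5% and 99.1% of cases, beside 86.2%, 81.9% and 84.8% in the simulations. All 11 rises and all 8 falls of day 1 were called the same way at day 10, as were 74 rises and 21 falls of day 3 and 689 rises and 368 falls of day 5. Independent lists of the same sizes would share 1.52 and 0.995, 11.2 and 2.74, and 98.1 and 47.6 genes, and 20 simulations of unchanged groups against the same controls shared 0, which says little, since no simulated comparison had more than 2 calls. Across genes, which are not independent replicates, the changes at day 1 and day 10 had r = 0.660 (simulated 0.624), those at day 3 and day 10 r = 0.741 (simulated 0.517) and those at day 5 and day 10 r = 0.867 (simulated 0.588). The covariance was 0.570, 0.783 and 0.879 in that order (simulated 0.143, 0.142 and 0.143). The 2 control libraries enter each of these comparisons and cannot be divided into parts of at least 2, and part of the excess over the simulated value can come from them. The 1057 genes called the same way at day 5 and day 10 became 1830 with DESeq2, 5 and 152 without control replicates 1 and 2, and 221 and 383 without day 5 replicates 1 and 3.

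Between day 1 and day 10, a comparison that needs no control library, 1466 genes rose and 1370 fell. Without uninoculated leaves of either day, it does not separate leaf age from time since inoculation. Manes.10G144300 rose from 25.5 ± 5.95 CPM (SD, n = 4) to 852 ± 287 CPM (SD, n = 3), and Manes.01G138500 from 0.625 ± 0.540 to 23.5 ± 12.6 CPM. Manes.01G070200 fell from 1065 ± 843 to 30.2 ± 16.1 CPM, beside 139 ± 34.3 CPM in the control (SD, n = 2). Manes.05G020800 fell from 22.1 ± 11.9 to 0.173 ± 0.0522 CPM, or from 525 counts in all day 1 libraries to 3 counts in all day 10 libraries, a scaled ratio of 116 (95% exact interval 39.6 to 566, counting error only). Of the day 10 rises against the control 1196 of 2375 (50.4%) were also called higher at day 10 than at day 1, and 959 of the 2132 falls (45%) were also called lower. Among all 17138 genes tested 1466 were called higher and 1370 lower. Both comparisons use the same day 10 libraries, which raises the overlap, and no value for unchanged groups was computed for it.

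The log2 changes were 5.05 (SE 0.58, adjusted p = 0.000711) for Manes.10G144300, 5.21 (SE 0.65, adjusted p = 0.000418) for Manes.01G138500, -5.14 (SE 1.28, adjusted p = 0.0241) for Manes.01G070200 and -6.94 (SE 1.22, adjusted p = 0.00396) for Manes.05G020800 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The call of Manes.01G070200 ended without any one of the day 10 libraries (adjusted p between 0.0587 and 0.100). The 2836 calls became 1889 when all libraries were thinned to equal depth, 1288 without day 10 replicate 2 and 1785 without day 1 replicate 3, and scaling to the total count gave 959 rises and 2544 falls with a median log2 change of all genes of -0.22.

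Comparisons of day 5 with day 1 and with day 10 were added after the data had been examined. Between day 1 and day 5, 79 genes rose and 64 fell (edgeR quasi-likelihood), and 61 of the rises and 43 of the falls were at least 2-fold. More genes fell than rose with DESeq2 (326 rose and 399 fell, 725 in all), without the day 3 libraries (209 and 270, 479 in all) and with limma-voom (81 and 108), so the balance of rises and falls depends on the setting. In the joint fit, leaving out day 1 replicates 1, 2 or 3 gave 31, 95 and 22, and day 5 replicates 1 or 3 gave 17 and 28. Between day 5 and day 10 edgeR called 0 genes, with 2337 at an unadjusted p under 0.05; limma-voom called 0, DESeq2 331, the fit without the day 3 libraries 5, and the fit without day 5 replicate 3 gave 4.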

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

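The tests of depth and of chance correlation in the co-varying genes, the test against the shift from abundant genes, and the comparison of day 5 with day 1, were chosen only after the result was seen. Day 1 replicate 2 had 11654930 total counts, far above the other day 1 libraries, the single such case among 25 values tested at a rate of about 5% by chance.

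The difference from the control changed between the sampling days. It differed between day 10 and day 1 for 2836 genes, and only 1 of the 35 divisions of those 7 libraries, the real division, gave as many, with 1863 in the next highest. That next division put day 1 replicate 4 with the day 10 libraries, which points to a structure within day 1. A share of 1 in 35 is the smallest that these divisions can give. It argues against a chance division of these libraries but does not exclude one, since the labels do not say that replicates are separate plants. Between day 5 and day 1 the difference from the control changed for 143 genes, and again 1 of 35 divisions gave as many, with 10 in the next highest. Between day 10 and day 5 the count was 0 and the highest other division gave 1; 10 of the 10 divisions gave as many, and 10 divisions are too few for a share under 0.05.

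A set of genes was picked for fitted values that were high at day 1 and lower later. At day 1, 104 genes lay at least 2-fold above the control and were called at least 2-fold lower at day 10 than at day 1, and 89 of them had a fitted value below the control at day 10, of which edgeR called 3 and DESeq2 4. None of the 104 was called against the control at day 1 by edgeR (0), while 71 had an unadjusted p under 0.05 and DESeq2 called 35.

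Falls at day 10 against the control numbered 2132 while a few abundant genes gained counts. Removing the 100 most abundant genes before scaling left 2100 falls and 97.98% of all calls. TMM scaling was used with and without those genes, and the median log2 change of all genes was -0.02 in both fits. This scaling already allows for counts taken by a few genes, so the removal could hardly change the calls. It therefore does not decide whether a loss of counts to those genes was a source of the falls. Abundant genes beyond those 100 were not removed. Between the group means the share of the 100 genes could shift all other genes by -0.25 on the log2 scale. Between the most distant control and day 10 libraries the shift was -0.27. In edgeR's glmTreat 1325 and 1223 genes fell by more than these shifts, which those 100 genes cannot account for. After thinning all libraries to equal depth 1556 fell, which argues against depth as the source. An effect of inoculation and an effect of leaf age remain open, since the day of the control leaves is not in the labels, and scaling to the total count gave 4198 falls, so the number rests on the TMM assumption that most genes do not move.

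Libraries of day 3 were far apart in a group of co-varying genes: 43 genes, made up of Manes.01G070200 and those with r above 0.95 to it over the 14 libraries, built on this gene after Manes.05G020800, with 3 counts at day 10, had given 12 genes, 11 of them in both groups. Because Manes.01G070200 itself differed between the day 3 libraries, the group was chosen again without them: all 42 genes found besides the seed were higher in day 3 replicate 1 than in replicate 2, with a median log2 ratio of 3.50, and of 3.19 after thinning (quartiles 1.69 and 4.29), which argues against depth. In 0 of 1000 shuffles of the seed gene were there as many genes as in the first group, although 23 of 500 other seed genes gave groups at least as large. Libraries were scored on a scale from the day 1 mean (0) to the day 10 mean (1), set without day 3. Day 3 replicate 1 scored 0.26 and replicate 2 0.57, the controls -0.07 and 0, and day 5 replicates 1 to 3 0.71, 0.41 and 0.63. Day 3 replicate 2 thus lay inside the day 5 range, and a day 5 library under its label was not tested. Each day 1 library was left out of the day 1 mean and of the choice of genes for its own score. Scored in this way, day 1 replicates 1 to 4 had 0.08, 0.07, 0.01 and 0.28, each on a slightly different scale from the other libraries. A day 1 library under a day 3 label and a plant that responded later cannot be told apart, since replicate 1 lies inside the day 1 range only through day 1 replicate 4 (without it the highest is 0.08), and the scale does not separate day 1 from the control. A different number of nymphs cannot be told apart from these either, since the labels do not give that number for each library.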

How the results depend on the processing

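All alternatives for the genes shared by day 5 and day 10, limma-voom and the fit of only the libraries compared for named genes, total-count scaling, thinning, removal of the 100 most abundant genes or of the day 3 libraries, and the comparisons of day 5 with day 1 and day 10 with day 5 were chosen only after the results were seen. Of the 157 alternative values for counts of genes, 100 lay within 1.5 times of the reported count and 57 did not; for 20 named changes under 324 settings the direction was the same in all, 276 also stayed past the threshold and 48 did not. The named genes were chosen for large changes with no overlap between the libraries compared, so their unchanged direction was largely fixed by that choice. The cause of a moved count or a lost call was not tested except where stated. DESeq2 gave 1032 genes at day 1, 956 at day 3, 1938 at day 5, 4840 over the 5 groups, 1830 shared by day 5 and day 10, 725 for day 5 against day 1 and 331 for day 10 against day 5. Without a filter on low counts there were 117 at day 1, 191 at day 3 and 12 for day 10 against day 5. Limma-voom gave 121 and a non-robust spread 12 at day 1. Total-count scaling gave 70 at day 1, 203 at day 3 and 4 for day 10 against day 5, with a median log2 change of all genes of -0.12 at day 1 and at day 5, and 554 rises with 556 falls at day 5. Thinning, which discards counts, gave 105 at day 1 and 1889 for day 10 against day 1. Without the day 3 libraries, which leaves their spread out of the fit, there were 478 at day 1, 479 for day 5 against day 1 and 5 for day 10 against day 5. With only the libraries compared there were 238 at day 1, 0 at day 3 (3044 genes at an unadjusted p under 0.05) and 1950 at day 5.

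Leaving out a library gave 0 to 568 genes at day 1, 0 to 361 at day 3, 5 to 1159 at day 5, 1548 to 4008 at day 10, 1288 to 3193 for day 10 against day 1, 17 to 146 for day 5 against day 1, 0 to 4 for day 10 against day 5, 1331 to 4154 over the 5 groups and 5 to 1102 shared by day 5 and day 10. With a single control or day 3 library left, that library is assumed to vary like the other groups. At day 1 the count was 0 without either control (1082 and 2383 genes at an unadjusted p under 0.05 without replicate 1 or 2), and 568 without day 1 replicate 2. The replicate block gave 4 genes at day 1, 59 at day 3, 62 for day 5 against day 1 and 1 for day 10 against day 5. For day 10 against day 1 it gave 2836, of which 2358 were among the 2836 reported calls with the same direction. Under it the calls of Manes.04G013900 and Manes.15G054200 at day 1 (adjusted p = 0.0760 each), Manes.10G021200 at day 3 (0.0570), Manes.12G055201 at day 5 (0.0590) and Manes.01G070200 between day 10 and day 1 (0.0664) ended in edgeR. Same-numbered libraries did not deviate together: of 23 pairs, with r from -0.25 to 0.24, 3 lay above 0.1, so the numbers were not taken to pair the samples. Tests of gene lists were not run, because no product names were paired with the IDs. Depth limits the genes with low counts, and the smallest library held 3137131 counts.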

Other observations

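The co-varying genes and the order of neighbouring IDs were examined only after the values were seen. The 43 co-varying genes were chosen for following Manes.01G070200, a gene named for its fall from day 1 to day 10, so their lower level at later days comes from that choice. Their median log2 level against the control mean was 2.19, 1.13, 1.61 and 2.77 in day 1 replicates 1 to 4, 1.71 and -1.87 in day 3 replicates 1 and 2, -2.07, -0.57 and -1.05 in day 5 replicates 1 to 3, and -1.32, -1.96 and -1.37 in day 10 replicates 1 to 3. Against the control at day 1 edgeR called 0, with adjusted p between 0.120 and 0.472 and 24 at an unadjusted p under 0.05, and at day 10 it called 1 of the 43. Within groups 33 of the 43, with Manes.01G070200 itself counted, kept r above 0.9 with that gene. The choice of genes at r above 0.95 over these same libraries raises this number. Among 500 other genes of similar level taken as the seed, the median number of further genes was 0 and the highest 141, and 23 of the 500 gave at least the 42 further genes found here.

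Of the groups with 2 libraries, the median SD of log2 CPM over genes was 0.169 in the control and 0.329 at day 3, and the share of genes with an SD above 1 was 2.68% and 12.8%. This difference was not tested.

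Genes with neighbouring ID numbers had slightly similar changes at day 10. The correlation of the log2 change between neighbours in ID order was r = 0.070 over 17119 pairs, a correlation across genes, which are not independent, and 0 of 1000 shuffles of the order reached it, with 0.027 as the highest. Runs of at least 5 neighbours called the same way numbered 5, beside a mean of 1.21 and a highest of 7 in the shuffles. Reads shared between similar neighbouring genes and joint regulation are possible explanations, and neither was tested. Across the 18 numbered groups of IDs the share of genes that rose at day 10 was 12% to 15.6% (permutation p = 0.739, 10000 resamples) and the share that fell 10.5% to 14% (permutation p = 0.775).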
